A study of Mus musculus with 6 samples.

How the data were processed

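Gene expression was measured in A20 cells, a B lymphoma line derived from a BALB/c mouse, on 6 Affymetrix whole-genome mouse arrays. Per the labels' protocols, total RNA was prepared with a column kit and turned into biotinylated cRNA. Each of 6 conditions had 1 array: untreated cells, cells kept with SP600125 for 24 h, cells stimulated with TGF-β for 12 h or 24 h, and cells stimulated for 12 h or 24 h in the presence of SP600125. Groups were taken from the sample titles. The titles name DMSO for the arrays without SP600125, so "untreated" and "without drug" here mean cells with DMSO and no SP600125. No condition was repeated, and nothing in the labels says whether the arrays came from separate cultures on separate days.

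The deposited values are 1 linear intensity, called a signal, for each probe set and array. They were made with GCOS 1.2, per the submitters' processing notes, and its settings are not given in the sources used here. On each of the 6 arrays the 2% trimmed mean of the deposited intensity values was 500.0, which is the mark of a global scaling of each array to 1 target. Detection calls and scanner images were not used here. Array medians lay between 69.3 and 80.9, and the ratio of the highest to the lowest, 1.17, was under the limit of 1.2 set for rescaling, so the signals were used as deposited. The number of arrays limits the precision that can be stated.

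The table held 45101 probe sets. In the platform annotation 34958 had 1 gene symbol, 932 had several and 9211 were not listed, and names were taken only from probe sets with 1 symbol. The gene identifier of 34754 of these was found in the reference gene table, and 0 symbols had to be updated. A gene was represented by its brightest probe set over the 6 arrays, which gave 18194 genes. Signals under the 50th percentile of all signals, 74.2, were set to that floor before log2 was taken. At least 1 array was above the floor for 12997 genes. A change from or to the floor is a bound and is written "at least". Changes were described by fold and log2 difference on the floored scale, which understates the change of dim genes.

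Each of 7 pairs of arrays was compared by a 2-fold rule, as in the study design: TGF-β at 12 h and 24 h without and with drug, each against the unstimulated array of the same arm, and SP600125 at 0 h, 12 h and 24 h of TGF-β. These pairs have no test. The tests came from limma 3.58.1 in R 4.3.3, run on 11698 genes above the floor on at least 2 arrays. An additive model with the 3 TGF-β states and the drug as terms used all 6 arrays and left 2 residual degrees of freedom, to which the variance prior with an intensity trend added 6.09. It gave the effect of 12 h and of 24 h of TGF-β averaged over both drug settings, each seen in 2 pairs, and the effect of SP600125 averaged over the 3 states, seen in 3 pairs. A further model, TGF-β by SP600125, took 12 h and 24 h as repeats of 1 TGF-β state, with a prior of 2.84 degrees of freedom, and gave the interaction and the TGF-β effect without drug. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The error in the additive model is the departure of single arrays from additivity, so its p-values measure only the spread between these arrays, and a true interaction counts as error there. "Rose" and "fell" are used of limma calls, and "higher" and "lower" of single pairs. Errors after ± are standard errors from limma.

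A TGF-β inducible gene was at least 2-fold higher at 12 h or 24 h without drug. It was called reduced when the increase in signal over the SP600125 array was over 75% smaller than the increase over the untreated array at every time with a 2-fold induction, and kept when it was under 25% smaller. The same rule was run on 100 data sets simulated from the additive fit with resampled residuals and no drug dependence. The drug arm at 12 h holds cells with 12 h of drug, while its unstimulated array holds 24 h of drug.

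There were 31 gene lists with 688 genes, 639 of which were found by symbol or an older name. They cover TGF-β and Smad feedback and targets, TGF-β ligands, receptors and Smads, the JNK cascade and AP-1, immediate-early genes and MAPK phosphatases, the BCL-2 family, caspases with death receptors and inhibitors of apoptosis, B cell identity, class switching and germinal centre, plasma cells, MHC class II presentation, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and pocket proteins, p53 targets, MYC and ribosome biogenesis, aryl hydrocarbon receptor targets, NRF2 and oxidative stress, NF-κB targets, cytokines with chemokines and receptors, interferon-stimulated genes, the unfolded protein and amino acid response, cholesterol synthesis, glycolysis and hypoxia, heat shock, adhesion and cytoskeleton, extracellular matrix, housekeeping genes, and markers of NK and T cells, myeloid cells, fibroblasts, and erythroid cells and platelets. Counts were adjusted over all genes tested and also over the list alone. For single pairs, a list's median was set among 10000 random lists of the same size matched on mean signal, as a description of these arrays.

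The lists, comparisons, thresholds, most of the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes with the largest change up and the 10 down shared by 12 h and 24 h of TGF-β without drug, and the 5 with the largest bounds among genes below the floor in untreated cells. It took the 10 up and 10 down shared by all 3 SP600125 pairs, the 10 most induced of the reduced genes and of the kept genes, up to 4 members of each list with the largest change in each comparison, the 10 up and 10 down with the smallest adjusted p of each limma effect, and always Smad7, Skil, Tgif1, Pmepa1, Id1, Id2, Id3, Junb, Jun, Bcl2l11, Cdkn1a, Myc and Cyp1a1. It made 402 genes eligible, of which 197 had another probe set above the floor. Other genes that the rule always takes are not reported here.

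Alternatives were median scaling and quantile normalization, no floor and a floor at the 75th percentile, the mean of all probe sets of a gene and probe sets specific to 1 transcript, other fold thresholds, baselines and cutoffs of the reduction, a variance prior without a trend, no filter on dim genes, and each TGF-β state left out. The fits without the array of TGF-β at 24 h with SP600125, the reduction at 12 h alone and the exchange of the arms were added after the data were seen. The limma models were tested on simulated data with 11698 genes, 100 of them changed by each fold. The changed genes were bright, with a mean signal over 4 times the floor. The simulated interaction was the same at 12 h and 24 h. The recovered shares may therefore be higher than recovery in these data. For the SP600125 effect 88% of 2-fold and 100% of 4-fold changes were recovered with 2 false calls. For the 24 h effect these were 75% and 100% with 2 false calls. For the interaction they were 3% and 49% with 0 false calls. Of simulated lists without a shift 4% lay outside the central 95% of random lists, and 100% did with a log2 shift of 0.5. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.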

Results

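A20 cells were stimulated with TGF-β for 0 h, 12 h or 24 h, each without and with SP600125, an inhibitor of the JNK kinases, and messenger RNA was measured on 1 array per condition. The design asks which genes TGF-β induces in these B lymphoma cells and which inductions are lost when JNK is inhibited. There were no replicates, so no comparison can be set against a replicate spread. The number of genes above the floor was 10448 in untreated cells, 10658 with SP600125, 10692 and 10786 with TGF-β at 12 h and 24 h, and 10860 and 11288 with TGF-β and SP600125 at 12 h and 24 h. The array of TGF-β at 24 h with SP600125 stood apart in its control probe sets. Its 18S ribosomal RNA signal was 5878.2 against 506.5 to 881.5 on the other 5, and its actin 3′/5′ ratio was 1.89 against 1.25 to 1.51.

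TGF-β raised feedback and target genes of its own pathway in A20 cells. In the additive limma model Smad7, which blocks the receptor, rose by a log2 of 2.16 ± 0.23 at 12 h and 2.31 ± 0.23 at 24 h, and Skil, a repressor of Smad transcription, rose by 1.65 ± 0.12 at 12 h. Id2 rose by 2.89 ± 0.20 at 12 h with a Benjamini-Hochberg adjusted p of 0.000517 in limma, higher in 2 of 2 pairs, and Id3 rose by 1.88 ± 0.16. Ldlrad4, a membrane inhibitor of the pathway, rose by 1.83 ± 0.35. Of 25 measured members of the TGF-β and Smad target list 7 rose at 12 h and 12 at 24 h while 0 fell, and adjusted over the list alone 8 rose and 1 fell at 12 h and 13 rose and 0 fell at 24 h. With the mean of all probe sets 3 rose at 12 h and 7 at 24 h. The pair without drug at 12 h had a list median of only 0.07, at percentile 59.3 of random lists, since Smad7, Skil, Id2 and Ldlrad4 carried the change while most members were near 0. Pmepa1, Id1 and Cyp1a1 were near the floor.

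Tgfbr1 rose by 1.65 ± 0.33 at 12 h and 2.17 ± 0.33 at 24 h, although another of its probe sets was lower in the 24 h pair with drug, and Tgfbr2 rose by 0.89 ± 0.18 and 1.10 ± 0.18. Of 14 ligands, receptors and Smads 3 rose at 12 h and 4 at 24 h while 0 fell, with the same counts adjusted over the list alone, but 0 rose at either time with the mean of all probe sets. In the JNK cascade and AP-1 list, Jund rose by 1.55 ± 0.13 at 12 h and 1.84 ± 0.13 at 24 h, with another probe set at −0.12 in the 12 h pair with drug, and Junb by 1.27 ± 0.20 at 24 h, while Jun did not pass. Among 19 members 1 rose at 12 h, and 4 rose at 24 h with 0 fallen; adjusted over the list alone 1 rose at 12 h and 4 rose and 1 fell at 24 h. Under median scaling 2 rose and 1 fell at 24 h, and with the mean of all probe sets 0 rose at 12 h and 2 at 24 h.

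Genes of MHC class II presentation rose with TGF-β. H2-Ob, a chain of the H2-O regulator of peptide loading, rose by 1.98 ± 0.09 at 12 h and by 2.29 ± 0.09 at 24 h, the latter with a Benjamini-Hochberg adjusted p of 8.55e-05 in limma and higher in 2 of 2 pairs. H2-Ab1 rose by 1.27 ± 0.22 and 1.51 ± 0.22, H2-Eb1 by 1.31 ± 0.23 and 1.53 ± 0.23, and Ifi30, a lysosomal thiol reductase, by 1.43 ± 0.18 and 1.25 ± 0.18. Of 14 genes of MHC class II presentation 10 rose and 0 fell at both times, and 11 rose at both times adjusted over the list alone. With the mean of all probe sets of a gene 1 rose at 12 h and 8 at 24 h. The costimulatory genes Cd86, Cd40 and Cd83 rose by 1.56 ± 0.32, 1.30 ± 0.28 and 1.99 ± 0.26 at 12 h, and by 2.12, 1.72 and 2.58 at 24 h. The chemokine receptors Cxcr4 and Cxcr5 rose by 1.60 ± 0.24 and 0.98 ± 0.23 at 12 h.

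NF-κB targets, interferon-stimulated genes and immediate-early genes rose in part of each list. Nfkbia and Nfkbie, inhibitors of NF-κB that it induces itself, rose by 1.28 ± 0.10 and 1.40 ± 0.14 at 24 h, and Relb by 1.62 ± 0.24, with another probe set of Nfkbie at −0.068 in the 12 h pair with drug. Of 21 NF-κB targets 4 rose at 12 h and 12 at 24 h with 0 fallen, and 6 and 14 rose adjusted over the list alone, but 0 and 10 rose with the mean of all probe sets. Irf7, a driver of the interferon response, rose by 2.08 ± 0.27 at 12 h and 2.59 ± 0.27 at 24 h, and Usp18 by 2.43 ± 0.31 at 24 h. Among 21 interferon-stimulated genes 4 rose at 12 h and 8 at 24 h with 0 fallen, and adjusted over the list alone 7 rose and 1 fell at 12 h and 11 rose and 0 fell at 24 h. With the mean of all probe sets 0 of them rose at 12 h and 7 at 24 h. Egr1 and Egr2, growth factor response genes, rose by 1.88 ± 0.23 and 2.87 ± 0.30 at 24 h. Of 22 immediate-early genes and MAPK phosphatases 3 rose at 12 h and 13 at 24 h with 0 fallen, against 6 risen and 1 fallen and 14 risen and 0 fallen adjusted over the list alone, and 2 and 10 risen with the mean of all probe sets. List medians without drug were 0.30 at 12 h and 0.84 at 24 h for NF-κB, 0.69 and 0.95 for interferon, and 0.46 and 0.54 for immediate-early genes. No test compared 24 h with 12 h. The immediate-early median at 24 h with drug was 0.97, on the array with 18S at 5878.2.

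Genes of ribosome biogenesis and of the cell cycle fell with TGF-β. Myc fell by 1.43 on the log2 scale at 12 h with a Benjamini-Hochberg adjusted p of 0.00425 in limma, lower in 2 of 2 pairs, and was at −0.87 ± 0.16 at 24 h. Polr1b, a subunit of RNA polymerase I, was at −1.28 ± 0.21 and −1.54 ± 0.21, and Srm, which makes spermidine, at −1.24 ± 0.12 and −1.34 ± 0.12. Of 31 MYC and ribosome biogenesis genes 1 rose and 16 fell at 12 h and 2 rose and 20 fell at 24 h, and adjusted over the list alone 2 rose and 19 fell and 3 rose and 22 fell. With the mean of all probe sets 3 fell at 12 h and 13 at 24 h. Cell cycle genes that fell at 24 h included Ccna2 at −1.09 ± 0.10, Mad2l1 at −1.24 ± 0.14, Cdk1 at −0.84 ± 0.13 and Mcm2 at −0.96 ± 0.16. Among 38 G1/S genes 0 rose and 1 fell at 12 h and 26 fell at 24 h, and among 39 G2/M genes 2 rose and 0 fell at 12 h and 1 rose and 24 fell at 24 h. Adjusted over the list alone, 4 G1/S genes fell at 12 h and 29 at 24 h, and 2 G2/M genes rose at 12 h and 1 rose and 29 fell at 24 h. With the mean of all probe sets 12 G1/S and 15 G2/M genes fell at 24 h. The CDK inhibitors Cdkn1b and Cdkn2b rose by 1.25 ± 0.19 and 1.06 ± 0.18 at 12 h. The fall of the cell cycle lists was larger in the pair with the array of 18S 5878.2, with G1/S medians of −0.48 without and −0.73 with drug, and G2/M medians of −0.49 and −0.68.

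**Figure D1:**
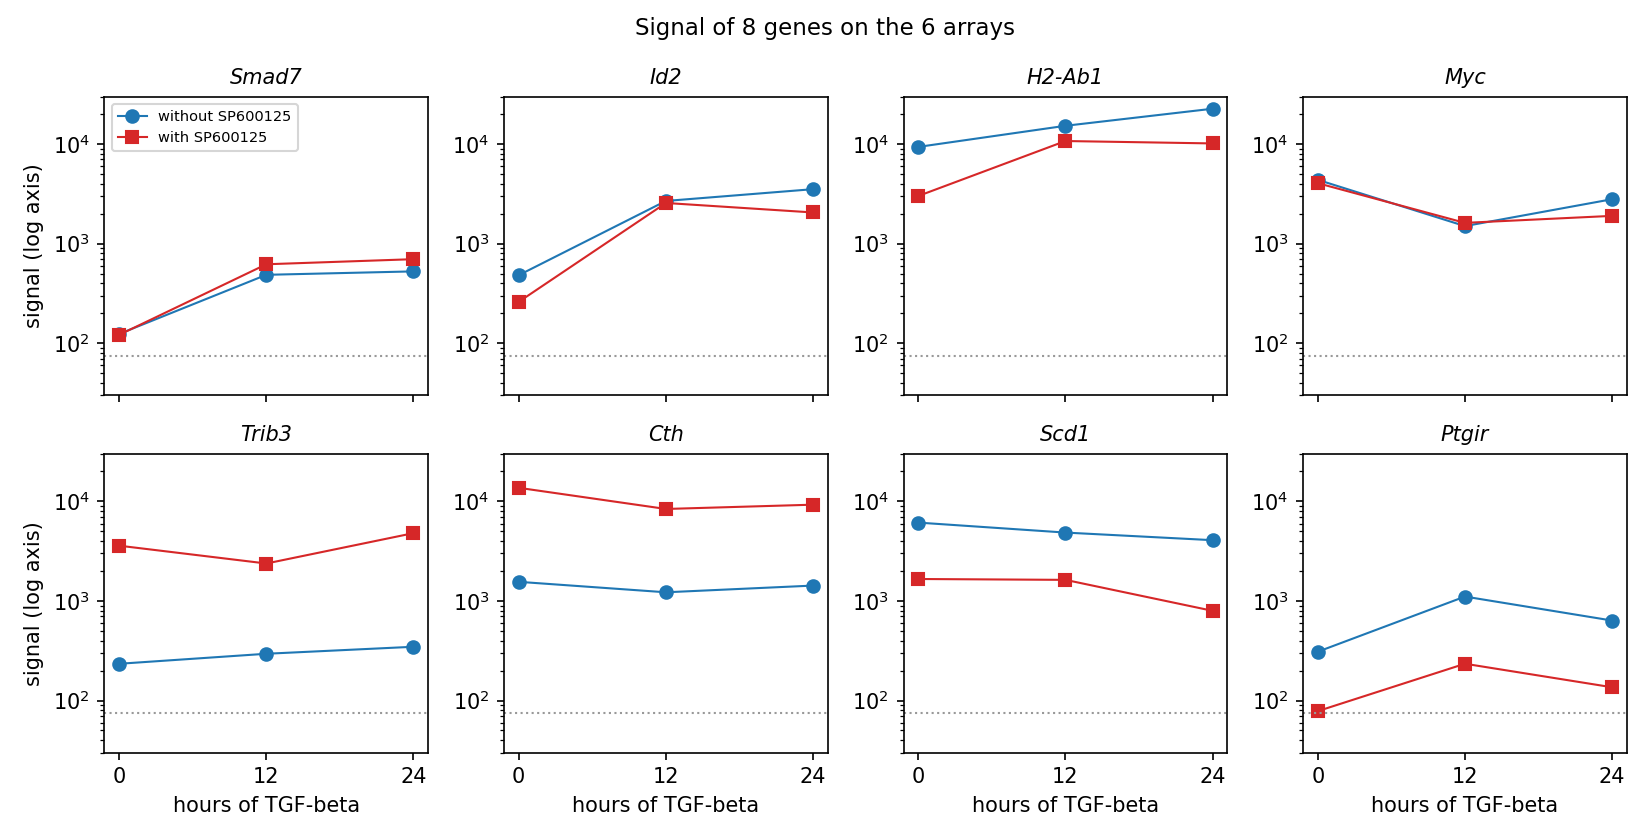
Array signal (log axis, arbitrary units) of 8 genes against hours of TGF-β, with blue circles for cells without and red squares for cells with SP600125, 1 array per point, and the floor of 74.2 as a dotted line. Smad7 and Id2 are higher at 12 h and 24 h than at 0 h in both arms, and Trib3 and Cth differ between arms at every time. The increase of Ptgir over 0 h is smaller in signal with SP600125.

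Without drug, 378 genes were at least 2-fold higher and 170 lower at 12 h of TGF-β, and 636 higher and 223 lower at 24 h. After median scaling of the arrays these became 319 and 255, and 522 and 329. Rgs2, a brake on G protein signalling, was higher by a log2 of 2.77 at 12 h and 3.01 at 24 h, and Cpm, a membrane carboxypeptidase, by 2.67 and 3.18. The apolipoprotein gene Apoc2 was 7.62-fold and 23.3-fold higher. Pck1, an enzyme of glucose synthesis that was below the floor in untreated cells, was at least 12.6-fold and 10.2-fold higher, and Il1r2, a decoy receptor for interleukin 1, at least 6.69-fold and 6.96-fold. Of the genes higher at 12 h, 257 were also higher at 24 h, where independent lists would share 18.5 and simulated noise around each gene's mean 11, and 84 were lower at both times against 2.92 and 18. Both pairs share the untreated array.

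The additive limma model called 320 genes risen and 292 fallen at 12 h, 612 in all, and 1072 risen and 888 fallen at 24 h, 1960 in all. Under median scaling these were 231 and 450 at 12 h and 680 and 1327 at 24 h. Of the calls 155 risen and 53 fallen genes at 12 h, and 385 and 104 at 24 h, also had a 2-fold effect. Without the array of TGF-β at 24 h with SP600125, limma called 0 genes at either time at a Benjamini-Hochberg adjusted p under 0.05, with 2333 at 12 h and 2645 at 24 h at an unadjusted p under 0.05. Without it no member of any list passed. The 24 h medians were then 1.06 for MHC class II against 0.98 and −0.59 for MYC and ribosome biogenesis against −0.57, but 0.58 for immediate-early genes against 0.89, −0.44 for G1/S against −0.61 and 0.80 for interferon against 0.57, and cholesterol synthesis turned from −0.05 to 0.16. That fit has 1 residual degree of freedom and a prior of 2.59. Its 24 h effect rests on the 1 array without drug, so these medians are not averaged over both drug settings. The shifts can thus hold a drug dependence of the TGF-β effect as well as the state of the array left out. The p-values measure only the spread between these arrays, which in this model is the departure from additivity.

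With SP600125 present, 8 of 25 Smad targets were at least 2-fold higher and 1 lower at 12 h of TGF-β, and 9 of 23 were higher at 24 h. Smad7 was higher by a log2 of 2.35 at 12 h and 2.52 at 24 h with drug, against 1.97 and 2.09 without, and Id2 by 3.30 and 2.98 against 2.48 and 2.87. Cd40 was higher by 1.82 and 2.43 with drug against 0.78 and 1.01 without, and H2-Ab1 by 1.83 and 1.75 against 0.70 and 1.27. Another probe set of Cd40 was at −1.36 with SP600125 alone, and at −0.21 and −0.20 at 12 h and 24 h of TGF-β. The MHC class II list median with SP600125 was −0.68 at 0 h, −0.31 at 12 h and −0.76 at 24 h. For Cd40 and the MHC class II list the larger log2 changes thus came with a lower drug-alone array, and not with higher levels under TGF-β. For the Smad target list the median change with SP600125 was 0.10 at 0 h, 0.24 at 12 h and 0.26 at 24 h. That list was thus not lower on the drug-alone array. The drug-alone array had 24 h of drug also in the 12 h pair. Tgfbr1 was higher by 0.92 and 1.36 with drug against 2.38 and 2.99 without, and Cxcr4 at 12 h by 1.08 against 2.11. The median of the MHC class II list was 1.2 at 12 h and 1.0 at 24 h with drug, against 0.70 and 0.95 without, and that of the MYC and ribosome list −0.55 and −0.52 against −0.61 and −0.58. The interferon list had 0.31 and 0.34 with drug against 0.69 and 0.95, and the NF-κB list 0.42 and 0.68 against 0.30 and 0.84.

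In the drug arm 291 genes were at least 2-fold higher and 152 lower at 12 h, and 541 higher and 234 lower at 24 h. Median scaling gave 242 and 205 at 12 h and 356 and 448 at 24 h, where it shifted the median of all genes in the 24 h pair by 0.17. Of the genes higher at 12 h without drug, 113 were also higher with drug, against 8.46 for independent lists, and at 24 h 218 were shared against 26.5. Across genes, log2 changes without and with drug had a Pearson r of 0.474 and a Spearman rho of 0.440 at 12 h, and 0.574 and 0.526 at 24 h. Genes are not independent replicates, and 5 such correlations were computed.

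SP600125 raised 16 and lowered 7 of 27 genes of the unfolded protein and amino acid response. Trib3, a pseudokinase induced by ATF4, was higher by a log2 of 3.94 at 0 h, 3.01 at 12 h and 3.79 at 24 h of TGF-β, and Cth, which makes cysteine, rose by 2.87 ± 0.10 with a Benjamini-Hochberg adjusted p of 3.15e-05 in limma, higher in 3 of 3 pairs. Atf4 itself rose by 1.49 ± 0.08, Atf5 by 2.49 ± 0.13, Cebpb by 2.87 ± 0.13, and Ddit3 by 2.14 ± 0.15, although another probe set of Ddit3 was lower in the 0 h pair. Members that fell included the chaperone genes Pdia3 at −0.90 ± 0.07, Pdia6 at −1.03 ± 0.09 and Hsp90b1 at −0.78 ± 0.12. Adjusted over the list alone 18 rose and 7 fell, and with the mean of all probe sets 10 rose and 4 fell. The list median was 0.77 at 0 h, 0.52 at 12 h and 0.74 at 24 h, above all random lists.

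Cholesterol synthesis genes fell with SP600125. Scd1, a fatty acid desaturase, was lower by −1.88, −1.58 and −2.36 at 0 h, 12 h and 24 h, and in limma was at −1.94 ± 0.14 with a Benjamini-Hochberg adjusted p of 0.000434, lower in 3 of 3 pairs. Lss was at −1.24 ± 0.13, Fdps at −1.16 ± 0.13, Fdft1 at −1.13 ± 0.11 and Cyp51 at −1.12 ± 0.11, all enzymes on the path to cholesterol. Of 23 members 0 rose and 21 fell, and 22 fell adjusted over the list alone, against 10 with the mean of all probe sets. Without the array of TGF-β at 24 h with SP600125 the limma median was −0.79 with 0 calls. The list median was −0.91 at 0 h, −0.67 at 12 h and −1.13 at 24 h.

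Some B cell genes, MHC class II genes and genes of DNA replication also fell with SP600125. Ptpn6, the phosphatase that restrains B cell receptor signalling, was at −1.34 ± 0.09, lower in 3 of 3 pairs with a Benjamini-Hochberg adjusted p of 0.000336 in limma. Cd22 was at −1.28 ± 0.14, Ms4a1, which encodes CD20, at −0.99 ± 0.09, and Ptprc at −0.96 ± 0.08. Another probe set of Ptprc was at −0.013 at 0 h, 0.33 at 12 h and −0.59 at 24 h. Of 25 B cell identity genes 0 rose and 10 fell, and 13 fell adjusted over the list alone, against 4 with the mean of all probe sets. H2-Ab1 was at −1.10 ± 0.18, H2-DMa at −1.10 ± 0.15 and Ifi30 at −1.04 ± 0.15. Another probe set of H2-DMa was at −0.49 at 0 h, 0.61 at 12 h and −0.89 at 24 h. Of 14 MHC class II genes 0 rose and 6 fell, and 1 rose and 11 fell adjusted over the list alone, but 0 fell with the mean of all probe sets. The list had medians of −0.68 at 0 h, −0.31 at 12 h and −0.76 at 24 h. Cdc6, a replication licensing factor, was at −0.97 ± 0.17, Rrm1 at −0.72 ± 0.11 and Tk1 at −0.65 ± 0.10. Of 38 G1/S genes 0 rose and 15 fell, and 1 rose and 23 fell adjusted over the list alone, but 1 fell with the mean of all probe sets. Its median was −0.60 at 24 h, on the array with 18S at 5878.2, against −0.35 and −0.27 at 0 h and 12 h. Of 39 G2/M genes 1 rose and 3 fell, and 1 rose and 13 fell adjusted over the list alone, but 10 fell under median scaling and 0 with the mean of all probe sets. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 1.38 ± 0.25, and the cell death genes Bbc3 and Bcl2l11 rose by 1.35 ± 0.21 and 0.74 ± 0.09.

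**Figure D2:**
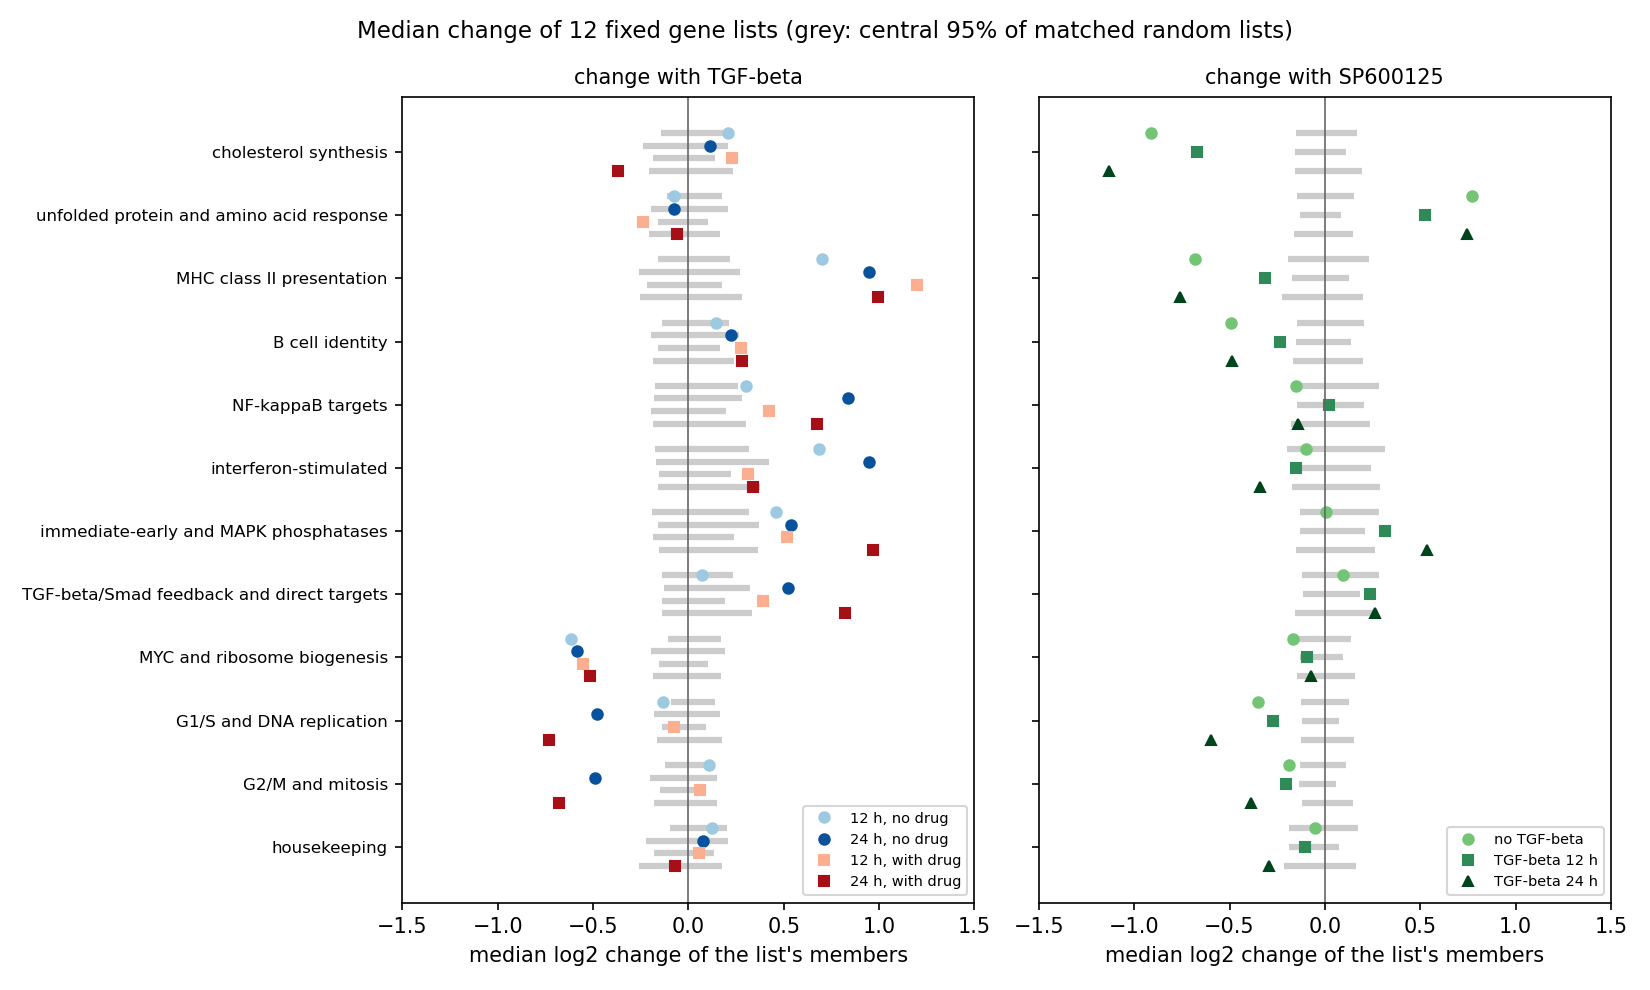
Median log2 change of 12 gene lists, on the left for TGF-β at 12 h and 24 h without and with SP600125 and on the right for SP600125 at 0 h, 12 h and 24 h of TGF-β, with the central 95% of matched random lists in grey. Cholesterol synthesis lies at −0.91, −0.67 and −1.13 in the SP600125 pairs, and MHC class II presentation at 0.70 and 0.95 in the TGF-β pairs without drug.

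By the 2-fold rule SP600125 made 364 genes higher and 150 lower in unstimulated cells, 210 and 130 at 12 h, and 375 and 230 at 24 h, where median scaling gave 238 and 322 with a shift of 0.13 in the median of all genes. In all 3 pairs 52 genes were higher, where independent lists would share 0.170, and 18 were lower against 0.0266. Prostacyclin receptor Ptgir was lower in all of them, at −1.98, −2.24 and −2.23. In limma 485 genes rose and 440 fell, 925 in all, of which 135 and 65 had a 2-fold effect, and under median scaling 349 rose and 678 fell. Without the array of TGF-β at 24 h with SP600125 limma called 0 genes for the drug at a Benjamini-Hochberg adjusted p under 0.05, with 1885 at an unadjusted p under 0.05.

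Inductions lost with the drug were sought among the 757 genes at least 2-fold higher at 12 h or 24 h without it. Sema3b, a secreted guidance factor, was 3.56-fold higher at 12 h, and its increase in signal was 85.8% smaller with SP600125. Tmem50b was 4.12-fold and 4.78-fold higher, with increases 92.8% and 79.7% smaller. Ptgir was 3.58-fold and 2.06-fold higher, with increases 80.5% and 82.4% smaller. Since SP600125 lowered Ptgir throughout, its log2 change at 12 h was still 1.58 with drug against 1.84 without. Adamts10, a metalloprotease, was 3.64-fold higher at 12 h with an increase 104.5% smaller, meaning that it was slightly lower with TGF-β in the drug arm. Irf2bpl was reduced by 123.2% and 78.9%, but another of its probe sets was lower at 12 h without drug. In all, 180 of the 757 genes, 23.8%, were reduced by over 75%, 216, or 28.5%, by under 25%, and 361 lay between. Genes that SP600125 itself raised can count as kept in signal with a smaller log2 change, as did Apoc2 with 1.78 at 12 h with drug against 2.93 without. Also kept were Pck1, Irf7, Cpm and Slc38a6, the last an amino acid carrier with 3.48-fold and 8.43-fold without drug and 7.17-fold and 15.9-fold with it.

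In data simulated without any drug dependence, the median number of reduced genes was 154 against 176 among the genes fitted. That many were reached in 1 of 100 draws. Any true interaction is part of the resampled residuals, so the simulated noise may be too large. Whether the resampling keeps departures that many genes share on an array was not checked. If it does not, the simulated ranges are too narrow. The simulation gave 864 inducible genes against 753, so the reduced share was 17.6% (15.2% to 20.5%) against 23.4%. Kept genes numbered 338 (306 to 377) against 216, and all 100 draws had more than were observed. Of 257 genes induced at both times 22 were reduced at both, against a simulated median of 11 with a range of 5 to 20. SP600125 alone raised 94 of the 180 reduced genes by at least 1.5-fold, against 290 of the 757 inducible genes and 1299 of 12997 genes above the floor on any array. A low untreated signal favours being called inducible, and a high SP600125 signal favours being called reduced. These differences in share are thus partly built into the rules. In untreated cells 66 of the 180 were below the floor, against 156 of the 757.

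**Figure D3:**
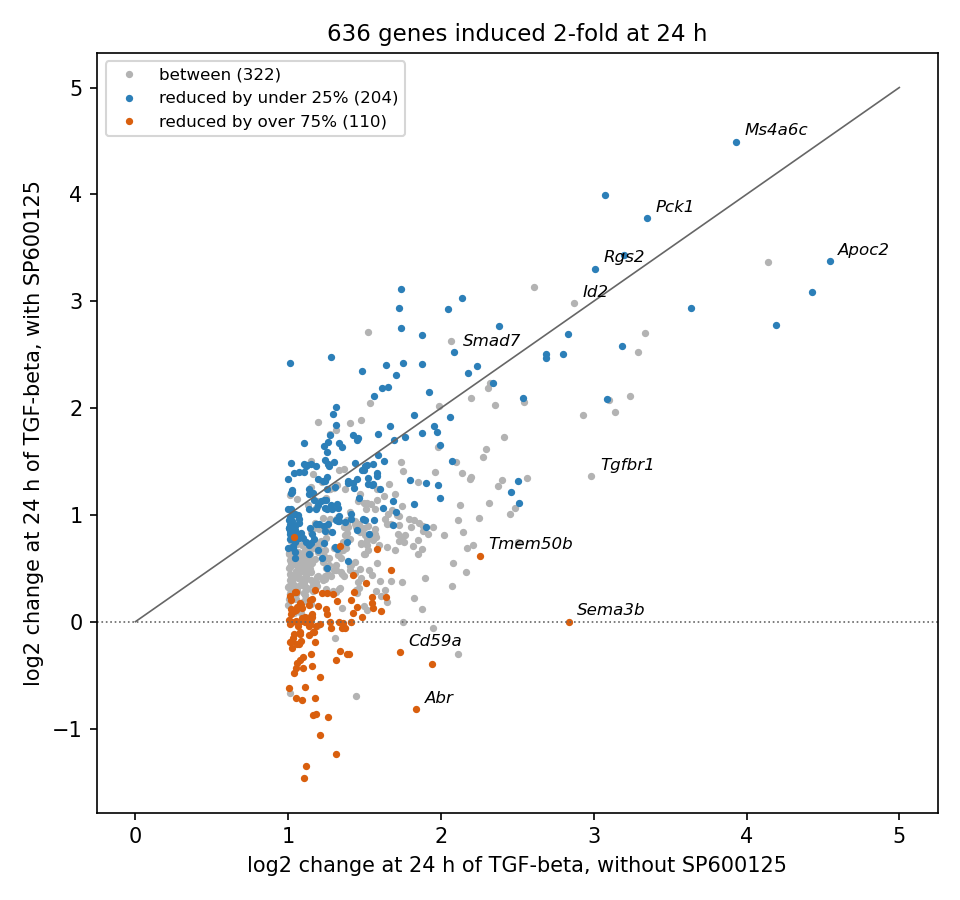
Log2 change by 24 h of TGF-β without SP600125 (x axis) and with it (y axis) for the 636 genes at least 2-fold higher without drug, with the diagonal marking equality. The increase in signal was reduced by over 75% in 110 genes and by under 25% in 204, 322 lay between, and 58 genes were lower with TGF-β in the drug arm.

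A dependence of the TGF-β effect on the drug was tested gene by gene as an interaction, taking 12 h and 24 h as repeats. Tmem50b had an unadjusted p of 0.00423 for the interaction in limma. It was picked as a reduced gene on these same arrays, for an induction smaller with drug at both times. No gene passed, with 0 calls by limma after Benjamini-Hochberg adjustment, 314 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.999. These 314 of 11698 genes are a smaller share than the 0.05 expected without any interaction. Without the filter on dim genes limma called 395 for the interaction and 217 for TGF-β without drug, of which 16 rose and 201 fell. A gene above the floor only on an unstimulated array has no spread between 12 h and 24 h in this model. Such calls cannot be read as interactions, but whether these genes make up the calls was not tested. With the filter, the TGF-β effect without drug in the same model also gave 0 calls by limma, with 1642 at an unadjusted p under 0.05 and a smallest adjusted p of 0.157. In simulated data the interaction test recovered 49% of 4-fold and 3% of 2-fold differences, so differences of that smaller size were not detectable. These shares hold for bright genes with the same difference at 12 h and 24 h, and recovery in these data may be lower.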

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

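The test with the arms exchanged, the tests of the array that stands apart, both tests of the MHC class II genes and the splits of the samples were chosen after the results were seen.

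The array of TGF-β at 24 h with SP600125 had a signal of 5878.2 on its 18S ribosomal RNA control probe set, which no comparison uses, where the other 5 arrays had 506.5 to 881.5. Its actin 3′/5′ ratio was 1.89 and its GAPDH ratio 0.976, the highest of the 6 arrays on both. No value in these data tells RNA state or labelling from an effect of the treatment on this array.

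Abr and Cd59a, the latter a protein that protects cells from complement, differed in direction between the 2 arms. Both were picked on these same arrays because their TGF-β changes had opposite signs in the 2 arms at both times. A difference in the same direction at both times therefore follows from the pick. The interaction p-values of these genes come from the values that picked them and are not separate support. Abr was higher with TGF-β by a log2 of 1.0 at 12 h and 1.84 at 24 h without drug, and changed by −0.45 and −0.82 with it, a mean difference of −2.05. Its interaction in limma had an unadjusted p of 0.0220 and a Benjamini-Hochberg adjusted p of 0.999, with the difference in the same direction at 2 of 2 times. Cd59a changed by 0.39 and 1.73 without drug and −0.75 and −0.29 with it, a mean difference of −1.58, and its limma interaction had an unadjusted p of 0.116 and a Benjamini-Hochberg adjusted p of 0.999, again in the same direction at 2 of 2 times. Another Cd59a probe set changed by 0.36 without and −0.46 with drug at 12 h, but was higher in both arms at 24 h, by 1.55 and 0.27, and it was higher by 1.38 with SP600125 alone. Neither passes.

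Of the TGF-β inducible genes, 180 had an increase over 75% smaller with SP600125. Whether this is a property of the drug arm stays open, since with the arms exchanged 27.9% were reduced against 23.8%, but the exchanged count of 169 was reached in 82 of 100 simulated draws against 1 of 100 for the real order, and of genes induced at both times 10 of 184 were reduced against 22 of 257. As shares of the fitted genes both orders, 26.6% exchanged and 23.4% real, lay above all 100 draws. The range of the draws may be too narrow if departures shared by many genes on an array were not kept. Noise in genes selected on the arrays without drug may give much of the count, because simulations without drug dependence had a median of 154, and stays open because the simulation had more inducible genes than the data. A higher baseline from the drug alone could account for part, as 43.9% of the reduced genes remained reduced with the untreated array as baseline of both arms. Drug dependence in single genes, the biological explanation, also stays open. Of the reduced genes 0 passed the limma interaction test, where 314 of all fitted genes had an unadjusted p under 0.05. Without any interaction a share of 0.05 would be expected there, and the observed share was smaller. The interaction test recovered only 49% of simulated 4-fold differences, in bright genes with the same difference at 12 h and 24 h.

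With SP600125 the median of the cholesterol synthesis list was lower and that of the unfolded protein and amino acid response list, in which 16 of 27 genes rose and 7 fell, was higher. The array that stands apart as the whole cause is argued against by the pairs without it, where the list median nearest to 0 was −0.67 for cholesterol synthesis and 0.52 for the unfolded protein and amino acid response. Scaling as the cause is argued against by the cholesterol median under quantile normalization, which was −0.68 in the pair nearest to 0. An effect of the inhibitor on these genes, through JNK or through another target, may remain as a hypothesis, and the design holds no further inhibitor to tell these apart.

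MHC class II genes were lower with SP600125. A drug-alone array that deviates by itself is argued against by the pairs at 12 h and 24 h, which do not use it and had a list median of −0.31 in the pair nearest to 0. Compression of bright probe sets is argued against by random lists of matched signal, among which the list stood at percentile 0.08 or lower in all 3 pairs. An effect of the inhibitor could remain as a hypothesis, found and tested on the same arrays.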

How the results depend on the processing

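The fits without the array of TGF-β at 24 h with SP600125, the reduction at 12 h only and the exchange of the arms were chosen after the data were seen.

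Values below are in the order TGF-β at 12 h and 24 h, SP600125 in unstimulated cells, TGF-β at 12 h and 24 h with drug, SP600125 at 12 h and 24 h of TGF-β, inducible genes and reduced genes. Against 548, 859, 514, 443, 775, 340, 605, 757 and 180, the counts without a floor were 4578, 4894, 4530, 4500, 4768, 4202, 4553, 3835 and 1705. Removing the floor can only enlarge a change, so by construction the counts of changed and inducible genes could only rise. For the reduced genes the cause was not tested. A floor at the 75th percentile gave 152, 322, 156, 124, 274, 76, 194, 240 and 26, since fewer genes lie above it. The mean of all probe sets gave 361, 572, 323, 286, 497, 206, 367, 503 and 101, for which the cause was not tested. By their construction a 1.5-fold threshold gave more, 2244, 2980, 2025, 1956, 2877, 1536, 2367, 2361 and 689, and a 3-fold threshold fewer, 100, 176, 106, 77, 131, 44, 72, 177 and 23. Induction required at both times gave 257 inducible and 22 reduced genes. Reduced genes were 103 with the untreated baseline, 326 with a 50% cutoff and 115 at 12 h only. They stayed within 1.5 times the reported count under median scaling (192), quantile normalization (160), specific probe sets (149), fold in place of signal (234), log2 change (178) and the time of larger induction (212). With the arms exchanged the count was 181, of other genes, since 1 gene is shared.

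The limma calls at a Benjamini-Hochberg adjusted p under 0.05 also moved under some alternatives. Against 925 genes for the drug, 612 at 12 h and 1960 at 24 h, the mean of all probe sets gave 175, 86 and 964, with 2457, 2316 and 3284 at an unadjusted p under 0.05, and a prior without trend gave 94, 20 and 570. With no floor 1005 genes were called at 12 h and 62 for TGF-β without drug, and probe sets specific to 1 transcript gave 609 for the drug. For these the cause was not tested, nor was it for a test of all genes, where limma called 0 for the drug (2300 at an unadjusted p under 0.05), 2 at 12 h, 3 at 24 h, 395 for the interaction and 217 for TGF-β without drug.

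Leaving out 1 TGF-β state left 0 to 126 calls for the drug in limma, 126 without 0 h, 36 without 12 h and 0 without 24 h, where 1884 had an unadjusted p under 0.05. With 0 h and 12 h only, limma called 0 genes at 12 h (2337 at an unadjusted p under 0.05), and with 0 h and 24 h only, 494 at 24 h. Without the array of TGF-β at 24 h with SP600125 limma called 0, 0 and 0, with 1885, 2333 and 2645 at an unadjusted p under 0.05, and fewer arrays leave 1 residual degree of freedom. For the drug and for 12 h this fit repeats the one without the 24 h state, since its lone 24 h array is fitted exactly. The interaction stayed at 0 limma calls under median scaling (394 at an unadjusted p under 0.05), quantile normalization (357), no floor (378), the 75th percentile floor (160), the mean of probe sets (414), specific probe sets (287) and no trend (398).

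Of 507 changes of at least 2-fold in named genes, 475 stayed at least 2-fold under median scaling, 486 under quantile normalization and 316 with the higher floor, with 0 reversed. Removing the floor cannot make such a change smaller. Of 349 values from other probe sets of the same genes 209 were at least 2-fold, 123 had the direction below 2-fold and 17 reversed. SP600125 in unstimulated cells gave −0.62 for Ddit3 and 0.44 for Srpk3, at 12 h −0.25 for Spsb1, and at 24 h 0.63 for Lsm6. TGF-β without drug gave at 12 h −0.72 for Irf2bpl, −0.25 for Sesn2 and −0.071 for Rngtt, and at 24 h −1.57 for Sesn2, −0.57 for Mxd4 and −0.58 for Mmp2. TGF-β with drug gave at 12 h −0.12 for Jund, −1.22 for Bmf and −0.068 for Nfkbie, and at 24 h −0.45 for Tgfbr1, −0.83 for Bmf, −0.60 for Cflar and −0.0078 for Ahr. The cause was not tested.

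For 94 list medians outside the random range, 466 alternative values were compared with the reported median. Of these, 434 stayed close to it relative to the width of the random range, 32 moved further away and 0 reversed. Whether the alternative values lay outside the random range was not checked. By limma on the mean of all probe sets, 10 cholesterol synthesis genes fell with the drug, and of MHC class II genes 1 rose at 12 h, 8 rose at 24 h and 0 fell with the drug. The precision is limited by signal over background above the floor, as the residual SD was 0.432 at a mean log2 signal of 6.99 and 0.103 at 13.6. At 6.29, near the floor, it was 0.140.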

Other observations

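The splits of the 6 samples were chosen as a test after the result was seen.

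TGF-β also changed some genes of adhesion, the cytoskeleton and cell death in A20 cells, though most members of these lists did not pass at 12 h. Vim, an intermediate filament, rose by a log2 of 2.21 ± 0.20 at 12 h, and Selplg, a selectin ligand, by 1.35 ± 0.24. Of 25 adhesion and cytoskeleton genes 5 rose and 0 fell at 12 h, 4 rose and 2 fell at 24 h, and 0 rose and 5 fell with SP600125, with Itga6 at −1.11 ± 0.16 (adjusted over the list alone 6 and 0, 7 and 4, and 1 and 9). In the BCL-2 family Bmf, a sensor of cell stress, rose by 1.96 ± 0.26 at 24 h, with another probe set lower in the drug arm, and Pmaip1 rose by 0.91 ± 0.14 at 24 h. Among 12 members 1 rose at 12 h, 3 at 24 h and 3 with drug, with 0 fallen (adjusted over the list alone 1 and 0, 5 and 1, and 5 and 1). Of 17 caspases, death receptors and inhibitors of apoptosis, 2 rose at 12 h, 7 at 24 h and 1 with drug, with 0 fallen, among them Fas by 1.13 ± 0.24 and Birc3 by 0.73 ± 0.10 at 24 h (adjusted over the list alone 6 and 0, 8 and 0, and 1 and 1). Under median scaling the adhesion counts at 24 h became 4 and 4, and the BCL-2 median at 12 h turned from 0.04 to −0.04. All these counts come from limma calls, written as risen and fallen, and none is left without the array of TGF-β at 24 h with SP600125.

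B cell differentiation genes moved both ways. Tnfrsf13b, the TACI receptor, rose by 1.28 ± 0.10 at 12 h and Bach2, which holds back plasma cells, by 1.06 ± 0.16 at 24 h, while Ung, which acts in class switching, was at −0.96 ± 0.20. Of 19 class switching and germinal centre genes 2 rose and 0 fell at 12 h, 5 rose and 2 fell at 24 h, and 2 rose and 1 fell with drug (adjusted over the list alone 6 and 2, 9 and 2, and 2 and 4). Of 25 B cell identity genes 2 rose and 2 fell at 12 h and 4 rose and 1 fell at 24 h with TGF-β, with Blnk at −0.73 ± 0.14 at 12 h and Fcrla up by 1.16 ± 0.18 at 24 h (adjusted over the list alone 3 and 3, and 5 and 1). Of 11 plasma cell genes 0 changed at 12 h, Ell2 rose at 24 h as 1 call, and 4 fell with drug, among them Creld2 at −1.19 ± 0.14 and Xbp1 at −0.42 ± 0.08 (adjusted over the list alone 0 and 0, 1 and 0, and 0 and 5). Of 17 cytokines, chemokines and receptors 2 rose at 12 h and 4 at 24 h with 0 fallen, and 1 rose and 3 fell with drug, where Vegfa rose by 2.07 ± 0.23 and Il10 was at −1.26 ± 0.31 (adjusted over the list alone 3 and 0, 4 and 0, and 3 and 3).

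Stress and metabolism genes had mixed changes. Trp53inp1, a p53 target, rose by 1.35 ± 0.30 at 12 h and by 1.35 ± 0.24 with drug. Of 17 p53 targets 1 rose and 1 fell at 12 h, 5 rose and 2 fell at 24 h, and 5 rose and 0 fell with drug (adjusted over the list alone 3 and 2, 6 and 2, and 7 and 1). Of 11 CDK inhibitors and pocket proteins 4 rose and 0 fell at both times, and 2 rose and 1 fell with drug (adjusted over the list alone 6 and 0, 5 and 0, and 2 and 1). Of 18 NRF2 and oxidative stress genes 2 rose and 0 fell at 12 h, 3 rose and 4 fell at 24 h, and 4 rose and 4 fell with drug, with Txnip up by 1.05 ± 0.11 at 24 h and Gsr at −0.79 (adjusted over the list alone 2 and 1, 4 and 5, and 4 and 5). Of 24 glycolysis and hypoxia genes 1 rose and 2 fell at 12 h, 3 rose and 7 fell at 24 h, and 2 rose and 6 fell with drug, where Tpi1 was at −0.75 ± 0.07 (adjusted over the list alone 1 and 3, 3 and 8, and 3 and 10). Of 11 heat shock genes 0 changed at 12 h, and 0 rose while 3 fell at 24 h and 2 with drug, with Hspd1 at −0.51 ± 0.09 at 24 h (adjusted over the list alone 0 and 0, 2 and 3, and 0 and 2). Ahr, the dioxin receptor, rose by 2.19 ± 0.27 at 24 h as the 1 call among 5 aryl hydrocarbon receptor genes, with 0 at 12 h and 0 with drug, although another of its probe sets was at −0.0078 in the 24 h pair with drug (adjusted over the list alone 1, 1 and 0 rose).

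With TGF-β, 1 of 27 genes of the unfolded protein and amino acid response rose and 2 fell at 12 h, and 3 rose and 3 fell at 24 h (adjusted over the list alone 1 and 5, and 3 and 3). Of 23 cholesterol synthesis genes 0 rose and 1 fell at 12 h and 1 rose and 4 fell at 24 h (adjusted over the list alone 4 and 2, and 2 and 4). With SP600125, Ski, a Smad repressor, rose by 1.06 ± 0.19 and Cdkn2b was at −0.91 ± 0.15, and 4 of 25 Smad targets rose and 1 fell (adjusted over the list alone 5 and 2). Smad4 rose by 0.58 ± 0.12 as the 1 call among 14 ligands, receptors and Smads (adjusted over the list alone 2 and 0). Of 19 JNK and AP-1 genes 1 rose and 1 fell, Batf rising by 0.63 ± 0.11 (the same adjusted over the list alone). Dusp5, a MAPK phosphatase, rose by 0.96 ± 0.14 and 2 of 22 immediate-early genes rose with 0 fallen (adjusted over the list alone 8 and 2). Eif4ebp1 rose by 1.60 ± 0.09, and of 31 MYC and ribosome genes 1 rose and 4 fell (adjusted over the list alone 3 and 8). Nfkb2 rose by 1.23 ± 0.14, and of 21 NF-κB targets 1 rose and 1 fell (adjusted over the list alone 1 and 5). Of 21 interferon-stimulated genes 0 rose and 3 fell, among them Psmb9 at −0.55 ± 0.10 (adjusted over the list alone 0 and 4).

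Of 12 extracellular matrix genes Adam19 rose by 1.17 ± 0.31 at 24 h as the 1 call, with 0 adjusted over the list alone. Limma called 0 of 6 NK and T cell, 0 of 4 fibroblast and 0 of 4 erythroid and platelet markers. Of 8 myeloid markers Cd68 rose at 24 h as 1 call, and 2 fell with drug, Cd68 at −1.27 ± 0.20, with the same counts adjusted over the list alone. Of 14 housekeeping genes 0 changed at 12 h, and 0 rose while 3 fell at 24 h and 2 fell with drug, with Tfrc at −0.73 and −0.52 (adjusted over the list alone 1 and 2, 3 and 3, and 1 and 5). Actb and Gapdh did not pass for the drug.

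With the mean of all probe sets of a gene most of these limma counts were lower. At 12 h, at 24 h and with drug, the numbers risen and fallen were 1 and 0, 3 and 0, and 0 and 1 for adhesion and cytoskeleton, 0 and 0, 1 and 0, and 1 and 0 for the BCL-2 family, and 0 and 0, 2 and 0, and 0 and 0 for caspases, death receptors and inhibitors of apoptosis. They were 1 and 0, 5 and 2, and 0 and 1 for class switching and germinal centre, 0 and 0, 0 and 0, and 0 and 2 for plasma cells, and 0 and 0, 3 and 0, and 1 and 1 for cytokines, chemokines and receptors. For p53 targets they were 0 and 0, 4 and 1, and 1 and 0, for CDK inhibitors 1 and 0, 2 and 0, and 0 and 1, for NRF2 0 and 0, 1 and 4, and 1 and 1, for glycolysis and hypoxia 0 and 0, 1 and 5, and 1 and 1, and for heat shock 0 and 0, 1 and 1, and 0 and 0. Housekeeping genes had 0 and 0, 0 and 2, and 0 and 1. The aryl hydrocarbon receptor list had 1 rise at 24 h, while extracellular matrix and myeloid markers had 0 calls. With TGF-β at 12 h and 24 h, B cell identity had 0 and 0, and 3 and 1, the unfolded protein and amino acid response 0 and 0, and 1 and 3, and cholesterol synthesis 0 and 0, and 0 and 2. With drug, Smad targets had 1 and 1, MYC and ribosome genes 1 and 2, immediate-early genes and NF-κB targets 1 and 0 each, and TGF-β ligands with receptors, JNK with AP-1 and interferon-stimulated genes 0 and 0 each.

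The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split by drug called 925 genes in limma and the highest other split 0, with 2824 and 842 at an unadjusted p under 0.05, so 1 of 10 splits gave as many. In the other splits a true drug effect counts as error, which leaves little room for calls. The contrast of 925 with 0 therefore does not decide the question.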
